A study of Mus musculus with 24 samples.

How the data were processed

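Messenger RNA of mouse bone marrow-derived macrophages was sequenced in 24 libraries, 3 for each of 4 treatments (vehicle, LPS, 4-OHE1 and both) at 6 h and at 24 h. The protocol states final doses of 100 ng/mL LPS and 5 mM 4-OHE1, but also stocks of these same concentrations diluted 1 to 1000, which would give 1000 times less, so the doses are uncertain. Per the submitters' processing notes, STAR, HOMER, DESeq2, edgeR and the mouse build mm10 were used, with versions not given in the sources used here. Per the file headers, the authors made the FPKM values with HOMER, as reads in the exons of 1 transcript per gene divided by its length and by the depth of the library, in 1 table for each time with 24537 genes each. No scaling between libraries was applied, per the file headers, and for 1114 genes the tables list different transcripts. The authors' deposited tables of 4 comparisons (LPS or 4-OHE1 against control, each time) hold log2 fold changes and adjusted p-values, per the file headers, and DESeq2 is named for them in the submitters' processing notes. They were used only as an alternative.

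Each FPKM was a whole number of reads, within a tolerance of 0.1 read, for 99.99% to 100% of the values checked per library, so reads per gene could be recovered. Depth was 8.13e6 to 13.34e6 reads per library, with 7.05e6 to 11.23e6 reads in genes. For the LPS+4-OHE1 libraries it was estimated from the value of 1 read, and for the others it was in the table headers. Between 9624 and 10674 genes reached 1 FPKM per library. The 24 pairs of replicates had Pearson correlations of log2 values across genes, which are not independent replicates, of 0.992 to 0.996, and differed by more than sampling noise (chi-square per degree of freedom 1.46 to 16.9), so every library was counted separately.

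FPKM values were tested with limma 3.58.1 in R 4.3.3 as log2(FPKM + 0.5), with the empirical Bayes trend, for genes at 1 FPKM or more in at least 3 libraries. The 12 libraries of a time shared one fit, and differences between the times came from a fit of all 24 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and every gene said to have risen, fallen, changed or to be higher or lower passed it, with values given for the others. Log2 differences carry the pseudocount, which understates the change of low genes. Unless a scaling is named, they are of unscaled FPKM values, and their SE does not cover the choice of scaling. A raw-count test had been allowed for in case counts were found, but the tables hold FPKM, so the test planned for such values was used.

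The choices of tests, gene lists, alternatives and the rule for named genes were made before the data were examined. The rule took 24 benchmark genes of LPS, antioxidant and stress responses. It also took the 8 largest rises and falls per comparison among called genes with non-overlapping groups and a mean of at least 5 FPKM in a group. From each list it took up to 4 called members with the largest change, or its most abundant member where none was called. This gave 148 to 157 genes per comparison, and which of them the text names was not fixed by the rule. Mmp8, Tyms, Mcm2 and Pcna are named at 24 h although not among the 4 largest changes of their lists. Non-overlap, which chance gives in 10% of genes for 3 libraries against 3, was not asked of interactions and time differences, and predicted, microRNA and small nucleolar genes were left out. Of 36 lists, 34 had measured members and were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison, and again with the estimated correlation and with fry. Lymphocyte and erythroid markers had 0 members past the filter.

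Because comparisons share libraries, 20 simulations of unchanged groups were run. The fits were tested on data simulated from the control levels, with few genes changed and about as many up as down. Such data hold no shift of most genes in one direction, so the rates that follow do not cover the shift found with LPS. All simulated groups were also given the spread of the control libraries. At 6 h, pairs of LPS+4-OHE1 libraries differed more than pairs of controls (chi-square per degree of freedom 10.1 to 16.9 against 2.17 to 5.07). The rates may therefore be too favourable for results that rest on LPS+4-OHE1, such as the interaction. For LPS against control at 6 h (11065 genes), 88.7%, 90.9% and 97.0% of genes changed 1.5-, 2- and 4-fold were recovered and 11 of 10871 unchanged genes called. For the interaction at 6 h (11064 genes) 70.1%, 81.8% and 93.7% were recovered, and for the time difference of LPS (11303 genes) 65.1%, 88.1% and 95.3%. Alternatives were pseudocounts of 0.1 and 1, other filters, robust empirical Bayes, median-of-ratios scaling, a replicate block, each library left out, and the authors' deposited tables. Limma's voom on the recovered reads, the division of the controls and the count of interactions limited by the value of 0 FPKM were added after seeing the data. Figures were drawn with matplotlib 3.10.9.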

Results

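RNA was sequenced from mouse bone marrow-derived macrophages, cells grown from the marrow of female C57BL/6J animals. The cells received ethanol vehicle (control), lipopolysaccharide (LPS, a bacterial cell wall component sensed by macrophages), 4-hydroxyestrone (4-OHE1, a catechol metabolite of estrone), or both. RNA was collected after 6 h or 24 h of treatment, giving 8 groups of 3 libraries and 24 libraries in all. Total depth was 8.13e6 to 13.34e6 reads per library, of which 83.0% to 87.2% fell in genes. At these depths a single read in a transcript of 2 kb was worth 0.0375 to 0.0615 FPKM. Nothing in the labels ties the 3 libraries of a group to separate animals or cultures, so the p-values measure the spread between these libraries only, which may be technical.

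The first principal component held 63.0% of the variance of the 6 h libraries and 67.6% of that of the 24 h libraries, with the control libraries at the lowest and the LPS libraries at the highest scores. LPS+4-OHE1 libraries lay between the LPS and the 4-OHE1 libraries on this axis at both times. At 6 h, LPS+4-OHE1 replicate 3 scored 4.27 on it, while replicates 1 and 2 scored 19.4 and 18.3.

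**Figure D1:**
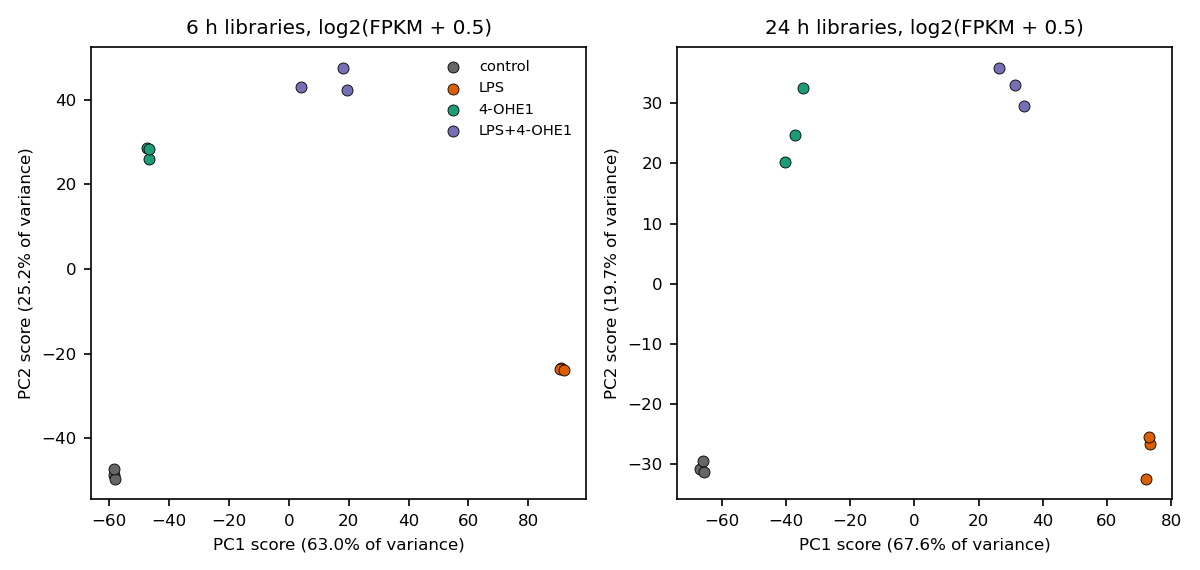
Scores of the 12 libraries of each time on the first and second principal components of log2(FPKM + 0.5), without units, one point per library and one colour per treatment. The 3 LPS+4-OHE1 libraries at 6 h lie between 4.27 and 19.4 on the first axis, away from every other group.

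The first question was what LPS alone did after 6 h. Il1b, Il6, Nos2 and Cxcl3 went from near the detection limit to far higher levels, while other inflammatory genes such as Tnf were present in control. Il1b, encoding the cytokine interleukin 1 beta (mm10 chromosome 2, 129364578 to 129371139), averaged 2675 ± 173 FPKM (SD, n = 3, as for all FPKM levels that follow) with LPS and 0.0377 ± 0.0652 FPKM in control, where the 3 libraries held 2 reads together. Il6, a fever-inducing cytokine (chromosome 5, 30013114 to 30019975), averaged 687 ± 12.2 FPKM against 0.0223 ± 0.0387 FPKM. The nitric oxide synthase gene Nos2 averaged 347 ± 12.7 FPKM against 0.00667 ± 0.0115 FPKM, and the chemokine Cxcl3 1312 ± 37.5 FPKM against 0.0683 ± 0.0598 FPKM. For these 4 genes the control libraries held 1 to 2 reads per group, so their log2(FPKM + 0.5) differences are no bound on the change. Tnf, at 18.2 ± 1.19 FPKM in control, rose by 7.33 ± 0.07 on the log2 scale (difference ± SE), to 3015 ± 72.8 FPKM. With median-of-ratios scaling its rise was 8.03, so the SE measures the spread between libraries and not the uncertainty from scaling. Of the inflammatory cytokines and chemokines, 33 of 34 members (33 adjusted over the list alone) rose (camera adjusted p = 3.56e-35, and adjusted p = 0.00768 with an estimated correlation). Interferon-stimulated genes, the antiviral program downstream of type I interferon, rose in 45 of 45 members (45 adjusted over the list alone, camera adjusted p = 3.88e-42, and adjusted p = 0.0862 with an estimated correlation). Cxcl10 rose by 9.45 ± 0.22, Rsad2 by 8.40 ± 0.19 and Gbp5 by 9.24 ± 0.14. Feedback inhibitors of the same signalling rose in 25 of 29 members (25 adjusted over the list alone, camera adjusted p = 6.70e-25, and adjusted p = 0.00545 with an estimated correlation). Socs3 rose by 7.24 and the anti-inflammatory cytokine Il10 by 4.78. LPS receptors and signalling genes rose in 14 of 21 members (14 adjusted over the list alone, camera adjusted p = 8.55e-10, and adjusted p = 0.00545 with an estimated correlation). Tlr2 rose by 3.83 and the LPS co-receptor Cd14 by 3.36.

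MHC class I presentation genes rose in 15 of 15 members (15 adjusted over the list alone) with LPS at 6 h (camera adjusted p = 1.06e-15, and adjusted p = 0.0862 with an estimated correlation). The peptide transporter Tap1 rose by 3.71 and the class I transactivator Nlrc5 by 3.50. MHC class II presentation genes rose in 5 of 7 members (5 adjusted over the list alone, camera adjusted p = 9.34e-05, and adjusted p = 0.303 with an estimated correlation). The cell cycle list fell in 32 of 32 members (32 adjusted over the list alone, camera adjusted p = 1.39e-06, and adjusted p = 0.459 with an estimated correlation). Cyclin D1, Ccnd1 (chromosome 7, 144929931 to 144939925), changed by -5.07, from 186 ± 4.71 FPKM to 5.05 ± 0.214 FPKM, and the ribonucleotide reductase subunit Rrm2 changed by -3.99. Other genes with large falls were the glycosyltransferase Gcnt1 (-6.08 ± 0.16) and the chemokine receptors Cxcr4 (-4.76 ± 0.15) and Cx3cr1 (-2.50 ± 0.11). Targets of NRF2, an antioxidant transcription factor, went both ways, with 18 of 41 members (18 adjusted over the list alone) higher and 18 of 41 members (18 adjusted over the list alone, 3 under both scalings) lower (camera adjusted p = 2.87e-04, and adjusted p = 0.417 with an estimated correlation). Mitochondrial antioxidants were higher in 2 of 14 members (2 adjusted over the list alone) and lower in 12 of 14 members (12 adjusted over the list alone, 5 under both scalings, camera adjusted p = 0.723, and adjusted p = 0.96 with an estimated correlation). The NRF2 target Nqo1 changed by -0.37 in the unscaled FPKM values, but by 0.32 with median-of-ratios scaling and by 0.31 in the authors' deposited comparison. The cystine transporter Slc7a11 rose by 6.09, mitochondrial superoxide dismutase Sod2 by 4.08, the peroxiredoxin Prdx5 by 2.79 and heme oxygenase Hmox1 by 0.70. With limma and Benjamini-Hochberg adjustment, 1792 genes were higher and 7563 lower among 11098 tested. The median gene lay at -0.61, and with median-of-ratios scaling, which set that median to 0.03, 4129 genes were higher and 3761 lower. Under both scalings 1792 were higher and 3759 lower, and 1097 were called in opposite directions. Single-gene differences with LPS at 6 h moved with the scaling too, as for Cd14 (4.06 when scaled), Hmox1 (1.40) and Ccnd1 (-4.40).

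The second comparison asked what 4-OHE1 did alone after 6 h. It raised stress-response genes of several kinds. The inducible heat shock protein gene Hspa1a (chromosome 17, 34969359 to 34972156) went from 0.490 ± 0.252 FPKM to 70.8 ± 7.39 FPKM, a rise of 6.20 ± 0.15, and its near-identical neighbour Hspa1b (34956429 to 34959238) rose by 5.94 ± 0.11. How reads were divided between these copies is uncertain. Heat shock genes rose in 19 of 27 members (19 adjusted over the list alone, camera adjusted p = 9.28e-11, and adjusted p = 0.0433 with an estimated correlation). Hmox1 (chromosome 8, 75093618 to 75100593) reached 10127 ± 284 FPKM from 1087 ± 73.8 FPKM, a rise of 3.22 ± 0.07. Targets of NRF2, the transcription factor of the antioxidant response, rose in 35 of 41 members (35 adjusted over the list alone, camera adjusted p = 1.42e-18, and adjusted p = 0.0433 with an estimated correlation). Slc7a11 (chromosome 3, 50364936 to 50443613) rose by 4.95 and the glutathione synthesis genes Gclc and Gclm by 3.06 and 1.14. Genes of the ATF4 integrated stress response, which follows phosphorylation of eIF2 alpha, rose in 30 of 32 members (30 adjusted over the list alone, camera adjusted p = 1.81e-19, and adjusted p = 0.0433 with an estimated correlation). Examples were Ppp1r15a (5.15 ± 0.08), Ddit3 (4.51 ± 0.10), Trib3 (3.96 ± 0.12) and Chac1 (2.81 ± 0.11), and the secreted stress marker Gdf15 rose by 3.91. ER chaperones rose in 10 of 19 members (10 adjusted over the list alone, camera adjusted p = 7.35e-04, and adjusted p = 0.0523 with an estimated correlation). Hspa5 rose by 1.83. Proteasome subunits rose in 28 of 31 members (29 adjusted over the list alone, camera adjusted p = 1.67e-10, and adjusted p = 0.144 with an estimated correlation). Psmd11 rose by 1.52. Hypoxia targets rose in 12 of 16 members (12 adjusted over the list alone, camera adjusted p = 2.20e-06, and adjusted p = 0.0433 with an estimated correlation). Vegfa rose by 2.79.

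Immune genes moved in both directions with 4-OHE1 alone at 6 h. Tnf rose by 2.47 ± 0.07 to 103 ± 9.41 FPKM, the chemokine Cxcl2 by 3.70 ± 0.13 and the cyclooxygenase Ptgs2 by 3.60 ± 0.19. Il1b, Il6 and Il12b averaged 0.109 ± 0.119, 0.125 ± 0.142 and 0.0447 ± 0.0427 FPKM with 4-OHE1, from 3 to 4 reads per group, and a difference from control (limma adjusted p of 0.359, 0.524 and 0.867) was not detectable at this depth. Of the inflammatory list, 12 of 34 members (12 adjusted over the list alone) rose (camera adjusted p = 9.04e-04, and adjusted p = 0.407 with an estimated correlation). Immediate early genes rose in 14 of 17 members (14 adjusted over the list alone, camera adjusted p = 2.05e-08, and adjusted p = 0.117 with an estimated correlation). The phosphatase Dusp1 rose by 3.11. The feedback inhibitors rose in 20 of 29 members (20 adjusted over the list alone, camera adjusted p = 3.12e-08, and adjusted p = 0.0524 with an estimated correlation). Nfkbiz rose by 3.77. Interferon-stimulated genes fell in 29 of 45 members (29 adjusted over the list alone, 26 under both scalings, camera adjusted p = 0.00192, and adjusted p = 0.707 with an estimated correlation). Cxcl10 changed by -2.23, Oas2 by -1.96 and Ifit1 by -1.48. The receptor gene Tlr2 changed by -2.82 ± 0.07, to 2.66 ± 0.121 FPKM, and Cx3cr1 by -2.42 ± 0.11. Cell cycle genes fell in 31 of 32 members (31 adjusted over the list alone, 30 under both scalings, camera adjusted p = 4.72e-09, and adjusted p = 0.261 with an estimated correlation). Ccnd1 changed by -2.68 and the mitotic kinase Plk1 by -2.51. In total, 2317 genes were higher and 4885 lower among 11098 tested with limma and Benjamini-Hochberg adjustment. With median-of-ratios scaling, which moved the median gene from -0.21 to -0.04, 3191 were higher and 3475 lower, and 2302 and 3474 were called in the same direction under both.

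**Figure D2:**
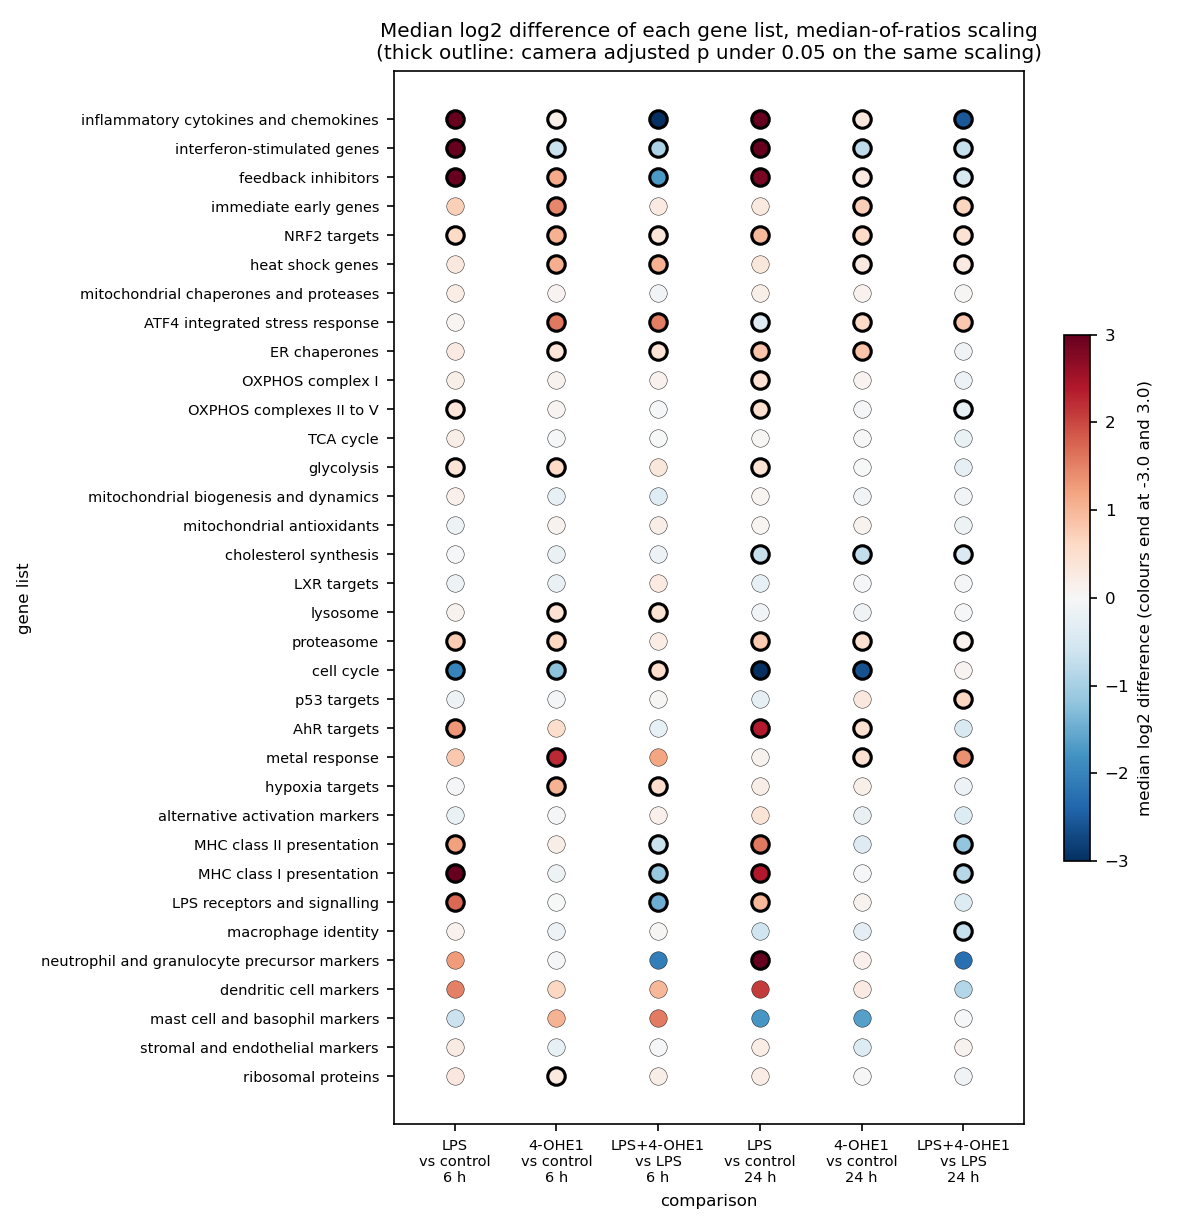
Median log2 difference of each gene list (rows) in 6 comparisons (columns) after median-of-ratios scaling; colour gives the median and a thick outline a camera adjusted p under 0.05 on that scaling, with the preset correlation. At 6 h the inflammatory list has a median of 7.45 for LPS against control and of -3.71 for LPS+4-OHE1 against LPS.

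The central comparison was of LPS+4-OHE1 with LPS, which shows what 4-OHE1 did to the response to LPS. At 6 h, Il1b was at 8.53 ± 1.60 FPKM in the cells given both, against 2675 ± 173 FPKM with LPS, a difference of -8.23 ± 0.15. Other cytokine genes were lower as well, with differences of -7.87 ± 0.19 for Il1a, -6.38 ± 0.19 for Il12b, -5.21 ± 0.31 for Il6 and -2.38 ± 0.07 for Tnf. Saa3, a serum amyloid gene of the acute phase (chromosome 7, 46711998 to 46715676), went from 2398 ± 373 FPKM to 4.86 ± 1.03 FPKM. Nos2 (-4.80) and Acod1, which makes the metabolite itaconate (-1.77), were lower. Inflammatory cytokines and chemokines were lower in 33 of 34 members (33 adjusted over the list alone, camera adjusted p = 7.52e-18, and adjusted p = 0.0835 with an estimated correlation). The anti-inflammatory cytokine Il10 (-3.69 ± 0.14) and the inhibitor Socs3 (-4.54 ± 0.12) were also lower, as were 23 of 29 members (23 adjusted over the list alone) of the feedback inhibitors (camera adjusted p = 3.72e-08, and adjusted p = 0.0835 with an estimated correlation). Receptors and signalling genes were lower in 15 of 21 members (16 adjusted over the list alone, camera adjusted p = 3.03e-05, and adjusted p = 0.0566 with an estimated correlation), with Tlr2 at -2.61, and Sod2 differed by -2.42. Interferon-stimulated genes were lower in 34 of 45 members (34 adjusted over the list alone, camera adjusted p = 1.23e-07, and adjusted p = 0.475 with an estimated correlation), with a median of -0.72 against -3.48 for the inflammatory list. Within it, Cxcl9 (-3.42) and Cxcl10 (-2.31) were lower, while Ifit1 averaged 652 ± 196 FPKM against 534 ± 10.6 FPKM (limma adjusted p = 0.284, and 0.0475 without LPS+4-OHE1 replicate 3).

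Stress genes were higher in LPS+4-OHE1 than in LPS at 6 h. The ATF4 list was higher in 30 of 32 members (30 adjusted over the list alone, camera adjusted p = 3.35e-10, and adjusted p = 0.155 with an estimated correlation). Trib3 rose by 5.53 ± 0.12, Sesn2 by 5.17 ± 0.14, Chac1 by 4.80 ± 0.11 and Ddit3 by 4.53 ± 0.10. Heat shock genes were higher in 23 of 27 members (23 adjusted over the list alone, 19 under both scalings, camera adjusted p = 3.03e-05, and adjusted p = 0.104 with an estimated correlation). Hspa1a rose by 5.60. NRF2 targets were higher in 32 of 41 members (32 adjusted over the list alone, 25 under both scalings, camera adjusted p = 5.29e-04, and adjusted p = 0.348 with an estimated correlation). Gclc rose by 2.96 and Hmox1 by 2.18, whereas Slc7a11, which each agent alone had raised, was lower (-1.27). Cxcr4 (5.05 ± 0.15), Ccnd1 (2.26 ± 0.16) and Vegfa (4.08 ± 0.11), which LPS alone had lowered (Vegfa by -1.79), were higher with both, as was the receptor Tnfrsf12a (5.67 ± 0.18). Of the cell cycle genes, 21 of 32 members (22 adjusted over the list alone, 19 under both scalings) were higher (camera adjusted p = 0.017, and adjusted p = 0.686 with an estimated correlation). MHC class I genes were lower in 12 of 15 members (12 adjusted over the list alone, camera adjusted p = 1.26e-04, and adjusted p = 0.348 with an estimated correlation). MHC class II genes were lower in 5 of 7 members (5 adjusted over the list alone, camera adjusted p = 0.0137, and adjusted p = 0.443 with an estimated correlation). By limma with Benjamini-Hochberg adjustment 4736 genes were higher and 2808 lower, or 3520 and 3920 with median-of-ratios scaling, which moved the median gene from 0.18 to -0.03. In the same direction under both scalings, 3513 were higher and 2799 lower. Without replicate 3 of LPS+4-OHE1, which stood apart on the first principal component, 4340 were higher and 2783 lower.

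Of the 953 genes that LPS raised at least 2-fold at 6 h, 781 (82.0%) were lower in LPS+4-OHE1 than in LPS and 82 were higher, with a median difference of -1.31 (783 lower adjusted over the list alone). For 576 of them the difference was at least 2-fold. Because the LPS libraries enter both comparisons, groups with no effect of 4-OHE1 were simulated, which gave 0% lower and a median of -0.007. Without an effect almost no gene is called, so the 0% was fixed in advance at both times, and only the median bears on the shared libraries. At 24 h, 605 of 881 LPS-raised genes (68.7%) were lower with both and 94 were higher, with a median of -0.78 (618 lower adjusted over the list alone), against 0% and -0.006 in the simulations. With the list of LPS-raised genes taken from the other time, 73.7% were lower, 100 were higher and the median was -1.11 at 6 h, and 56.8%, 152 and -0.42 at 24 h. The number of LPS-raised genes depended on the scaling. With median-of-ratios scaling 1634 genes were raised at least 2-fold at 6 h, of which 1306 (79.9%) were lower with both and 158 higher. At 24 h 1229 were raised, with 879 (71.5%) lower and 106 higher. The authors' deposited tables called 1977 genes at least 2-fold higher with LPS at 6 h and 1554 at 24 h.

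**Figure D3:**
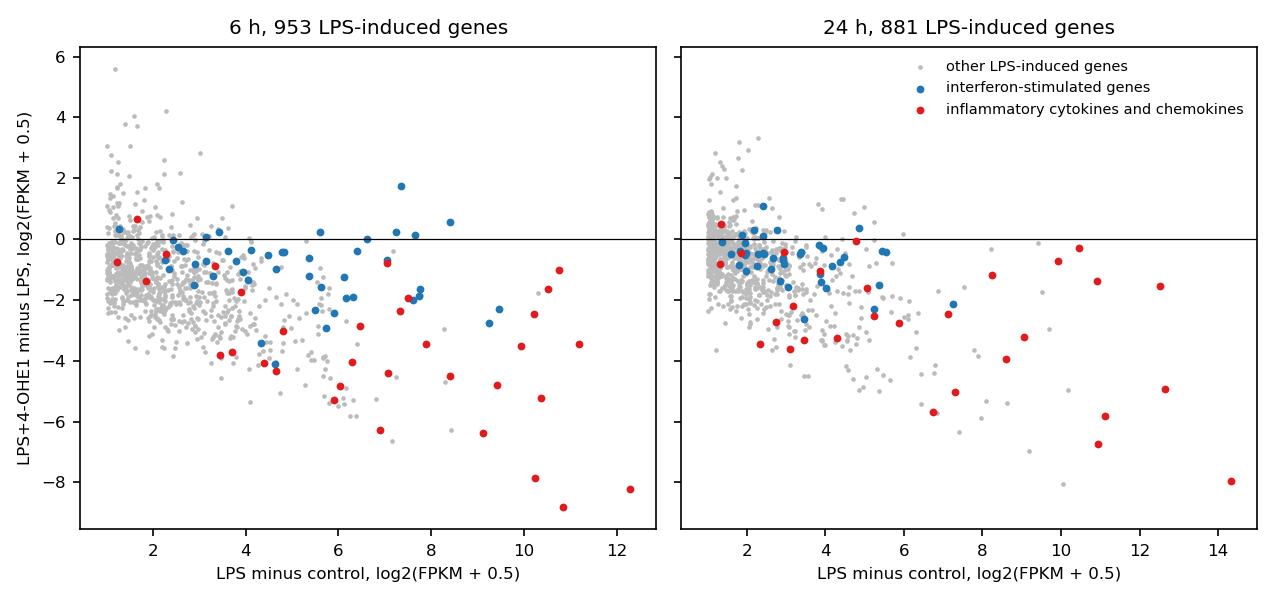
Each point is a gene raised at least 2-fold by LPS, with its log2 difference between LPS and control on the horizontal axis and between LPS+4-OHE1 and LPS on the vertical axis; colours mark the inflammatory and interferon-stimulated lists. Without scaling between libraries, 781 of the 953 genes at 6 h were called lower with both, and 605 of the 881 at 24 h.

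Whether the effects of LPS and 4-OHE1 added up on the log2 scale was tested as their interaction. At 6 h the interaction was negative for 33 of 34 members (33 adjusted over the list alone) of the inflammatory list (camera adjusted p = 2.60e-30, and adjusted p = 0.012 with an estimated correlation). Interactions were -8.39 ± 0.22 for Il1b, -7.11 ± 0.27 for Ptgs2, -5.45 ± 0.44 for Il6 and -4.85 ± 0.10 for Tnf. Slc7a11 and Socs3 both gave -6.22. The interferon-stimulated genes split, with 14 of 45 members (15 adjusted over the list alone, 11 under both scalings) positive, 14 of 45 members (15 adjusted over the list alone) negative and a median of 0.05 (camera adjusted p = 0.0661, and adjusted p = 0.936 with an estimated correlation). Cxcl10 gave -0.08 ± 0.31 (limma adjusted p = 0.843), Ifit1 1.72 ± 0.28 (1.75 with limma's voom, adjusted p = 0.0556), and Cxcl11 -4.05 ± 0.19. Cell cycle genes had positive interactions in 32 of 32 members (32 adjusted over the list alone, camera adjusted p = 2.84e-10, and adjusted p = 0.36 with an estimated correlation), with Ccnd1 at 4.94. For 2 of these 32, and for 340 of all genes with a positive interaction at 6 h, the sum of the single effects lay below the lowest possible value, that of 0 FPKM, which fixes part of the interaction in advance. With limma and Benjamini-Hochberg adjustment, 5050 genes had a positive and 1684 a negative interaction, or 2739 and 3206 with median-of-ratios scaling, which moved the median gene from 0.33 to -0.05. Under both, 2737 were positive and 1679 negative.

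Against 4-OHE1 alone, LPS+4-OHE1 showed what LPS still did in the presence of 4-OHE1 at 6 h. Interferon-stimulated genes rose in 45 of 45 members (45 adjusted over the list alone, camera adjusted p = 2.52e-72, and adjusted p = 0.0234 with an estimated correlation). Cxcl10 rose by 9.38, Rsad2 by 9.02 and Ifit1 by 8.97. The inflammatory list rose in 26 of 34 members (27 adjusted over the list alone, camera adjusted p = 8.96e-34, and adjusted p = 0.00991 with an estimated correlation). Acod1 rose by 9.10, the chemokine Ccl5 by 9.12 and Il1b by 3.89. Il10 averaged 3.26 ± 0.796 FPKM against 3.07 ± 0.444 FPKM (limma adjusted p = 0.743), and the costimulatory receptor Cd28 was lower (-2.16). Here limma with Benjamini-Hochberg adjustment called 1125 genes higher and 5576 lower, and with median-of-ratios scaling 2314 and 2003, a total of 4317 in place of 6701. The scaling moved the median gene from -0.28 to -0.01. Under both, 1124 were higher and 2000 lower, and 13 were called in opposite directions.

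After 24 h of LPS alone, the inflammatory list was still raised in 29 of 32 members (29 adjusted over the list alone, camera adjusted p = 4.17e-23, and adjusted p = 0.0271 with an estimated correlation). Saa3 reached 25280.0 ± 2946 FPKM from 0.728 ± 0.0859 FPKM, and Il1b 4328 ± 157 FPKM from 0.192 ± 0.170 FPKM. Lcn2, an iron-sequestering acute phase protein, averaged 1107 ± 93.9 FPKM against 0.0673 ± 0.117 FPKM, Cxcl3 3345 ± 172 FPKM against 0.0843 ± 0.146 FPKM, and Il6 214 ± 34.3 FPKM against 2 reads in the 3 control libraries together. The control libraries held at most 8 reads per group of Il1b, Lcn2 and Cxcl3. Interferon-stimulated genes were raised in 42 of 42 members (42 adjusted over the list alone, camera adjusted p = 2.18e-31, and adjusted p = 0.0308 with an estimated correlation). Cxcl10 rose by 3.88. Feedback inhibitors were raised in 25 of 27 members (25 adjusted over the list alone, camera adjusted p = 1.42e-17, and adjusted p = 0.0271 with an estimated correlation). NRF2 targets were raised in 28 of 42 members (28 adjusted over the list alone, camera adjusted p = 1.77e-09, and adjusted p = 0.181 with an estimated correlation). Slc7a11 rose by 5.96 and Nqo1 by 1.36, and Sod2 and Prdx5 rose by 5.09 and 4.59. MHC class I genes were raised in 15 of 15 members (15 adjusted over the list alone, camera adjusted p = 4.18e-13, and adjusted p = 0.0878 with an estimated correlation). MHC class II genes were raised in 5 of 6 members (5 adjusted over the list alone, camera adjusted p = 6.83e-04, and adjusted p = 0.181 with an estimated correlation). H2-Ab1 rose by 3.01. Targets of the aryl hydrocarbon receptor were raised in 6 of 6 members (6 adjusted over the list alone, camera adjusted p = 9.05e-06, and adjusted p = 0.0878 with an estimated correlation). Cyp1b1 rose by 3.30. The ER chaperones were raised in 14 of 19 members (14 adjusted over the list alone, camera adjusted p = 1.77e-06, and adjusted p = 0.0878 with an estimated correlation). The cholesterol exporter Abca1 rose by 4.09, while cholesterol synthesis genes fell in 19 of 23 members (19 adjusted over the list alone, 17 under both scalings, camera adjusted p = 0.00922, and adjusted p = 0.0878 with an estimated correlation). Dhcr7 changed by -2.35.

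Cell cycle genes fell in 32 of 32 members (32 adjusted over the list alone) with LPS at 24 h (camera adjusted p = 6.59e-12, and adjusted p = 0.0878 with an estimated correlation). Ube2c changed by -6.22 ± 0.31 and cyclin B2, Ccnb2, by -6.16 ± 0.19. The ATF4 list fell in 24 of 32 members (24 adjusted over the list alone, 20 under both scalings, camera adjusted p = 0.08, and adjusted p = 0.641 with an estimated correlation). Pck2 changed by -2.66. The macrophage marker Adgre1 rose by 2.78 and Cx3cr1 changed by -3.50. Of 15 neutrophil and granulocyte precursor markers only 5 passed the filter. They rose in 5 of 5 members (5 adjusted over the list alone, camera adjusted p = 9.05e-06, and adjusted p = 0.0405 with an estimated correlation). These were Mmp9, at 38.7 ± 1.43 FPKM, S100a8, at 48.8 ± 9.87 FPKM, Mmp8, at 30.2 ± 0.541 FPKM, Csf3r, at 16.2 ± 1.07 FPKM, and Camp, at 4.84 ± 1.70 FPKM and listed at 0 in control, whereas S100a9 averaged 0.201 ± 0.222 FPKM. Camp and Mmp9, which rose by 6.14, were under 1 FPKM in control. They passed the filter only through treated libraries, which favours a rise. In all, limma with Benjamini-Hochberg adjustment called 2231 genes higher and 5980 lower of 11185 tested, or 3980 and 3703 with median-of-ratios scaling, which moved the median gene from -0.31 to 0.03. Under both scalings 2228 genes were higher and 3703 lower, and 140 were called in opposite directions.

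After 24 h of 4-OHE1 alone, stress genes were still above control. Hspa1a averaged 107 ± 28.6 FPKM against 0.252 ± 0.0159 FPKM (7.13 ± 0.23), with the same doubt about the division of reads from Hspa1b (6.78 ± 0.20). NRF2 targets were raised in 35 of 42 members (36 adjusted over the list alone, 32 under both scalings, camera adjusted p = 5.97e-12, and adjusted p = 0.221 with an estimated correlation). Nqo1 (chromosome 8, 107388225 to 107403205) rose by 3.02 ± 0.07, Slc7a11 by 3.29 ± 0.14, the glutathione transferase Gsta4 by 3.06 ± 0.14 and Hmox1 by 0.46 ± 0.09. ER chaperones were raised in 17 of 19 members (17 adjusted over the list alone, camera adjusted p = 3.18e-10, and adjusted p = 0.0827 with an estimated correlation). Hspa5 rose by 1.86. Proteasome subunits were raised in 31 of 31 members (31 adjusted over the list alone, 30 under both scalings, camera adjusted p = 5.74e-10, and adjusted p = 0.249 with an estimated correlation). Psmd11 rose by 1.17. The ATF4 list was raised in 26 of 32 members (26 adjusted over the list alone, 24 under both scalings, camera adjusted p = 4.28e-08, and adjusted p = 0.249 with an estimated correlation). Ddit3 rose by 3.08 and Ppp1r15a by 3.09. Immediate early genes were raised in 14 of 17 members (14 adjusted over the list alone, 13 under both scalings, camera adjusted p = 7.76e-06, and adjusted p = 0.197 with an estimated correlation). Large single rises were those of the ion pump modulator Fxyd2 (4.19 ± 0.23), the betaine transporter Slc6a12 (4.15 ± 0.13) and Ptgs2 (2.47 ± 0.21). Interferon-stimulated genes were lower in 37 of 42 members (37 adjusted over the list alone, camera adjusted p = 5.44e-13, and adjusted p = 0.206 with an estimated correlation). Cxcl10 changed by -3.00, Ifit1 by -2.24 and the interferon regulator Irf7 by -2.11. Cell cycle genes were lower in 32 of 32 members (32 adjusted over the list alone, camera adjusted p = 6.21e-24, and adjusted p = 0.0605 with an estimated correlation). Ccnb2 changed by -3.64 and the proliferation marker Mki67 by -3.57. Cholesterol synthesis genes were lower in 19 of 23 members (19 adjusted over the list alone, camera adjusted p = 7.57e-09, and adjusted p = 0.00825 with an estimated correlation), including Stard4 (-1.50) and Hmgcs1 (-1.17), and Cx3cr1 changed by -1.93. The limma calls, with Benjamini-Hochberg adjustment, were 3344 genes higher and 2584 lower, or 2689 and 3166 with median-of-ratios scaling, with 2689 and 2578 shared.

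**Figure D4:**
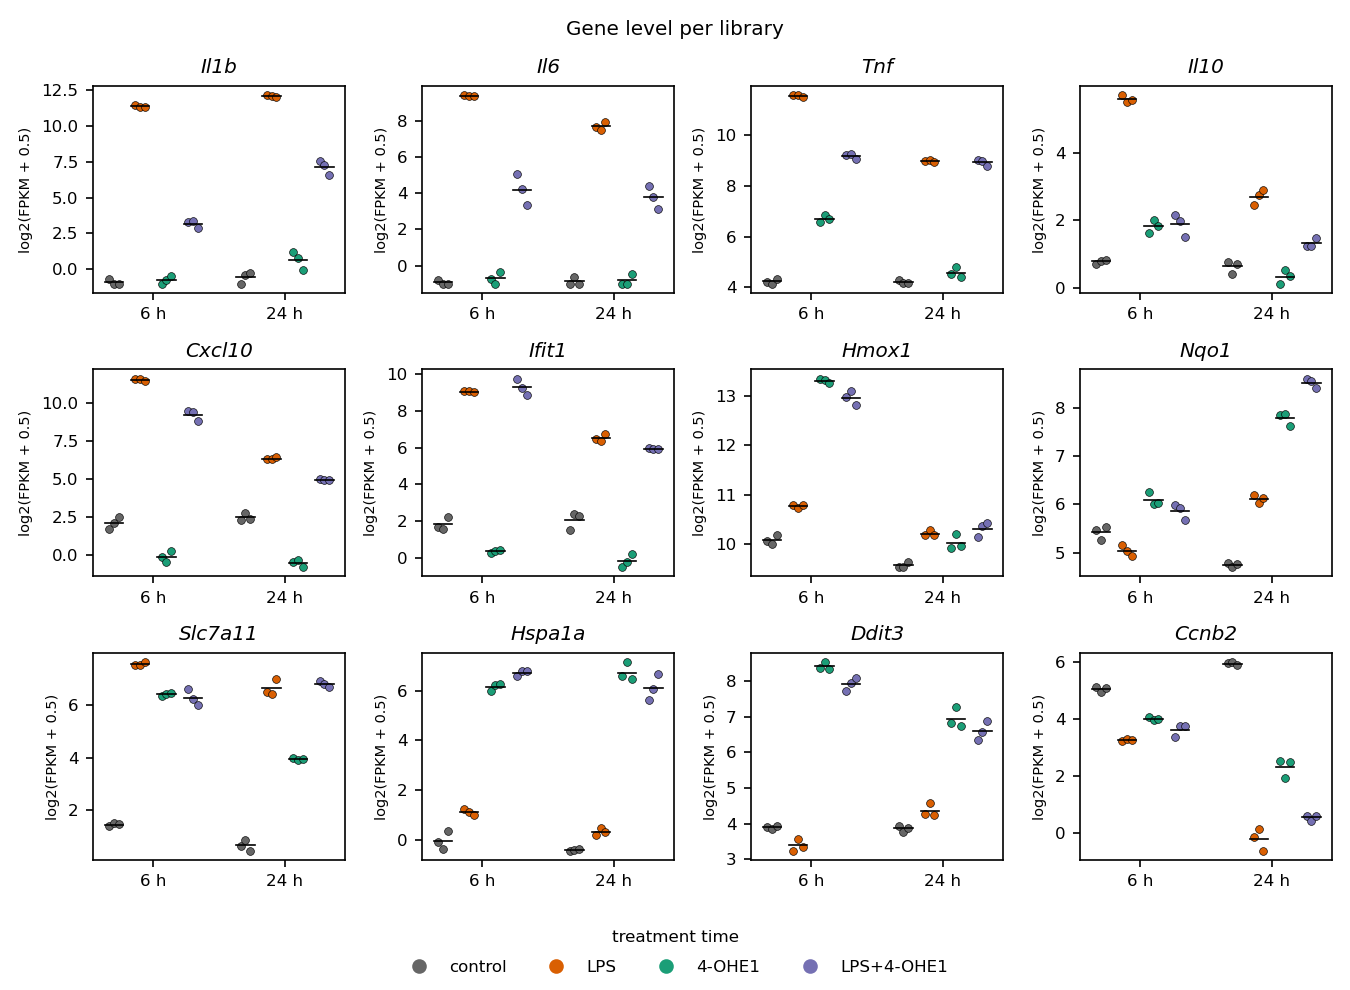
Levels of 12 genes as log2(FPKM + 0.5) in each library, grouped by time (horizontal axis) and coloured by treatment, with a line at each group's mean; n = 3 per group. Tnf in LPS+4-OHE1 lies below LPS at 6 h (581 ± 37.3 against 3015 ± 72.8 FPKM) and beside it at 24 h (489.8 ± 43.0 against 505 ± 18.5 FPKM).

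At 24 h, U90926, a transcript annotated as noncoding, was lower in LPS+4-OHE1 than in LPS, from 532 ± 35.4 FPKM to 1.68 ± 1.04 FPKM, and Saa3 averaged 106 ± 36.2 FPKM against 25280.0 ± 2946 FPKM. The scavenger receptor Marco (-6.96 ± 0.15), Lcn2 (-6.73 ± 0.33), Il12b (-5.02 ± 0.32), Il1b (-4.94 ± 0.31), Il6 (-3.95 ± 0.26) and Nos2 (-2.76 ± 0.16) were lower. Inflammatory genes were lower in 26 of 32 members (26 adjusted over the list alone, camera adjusted p = 2.15e-16, and adjusted p = 0.0511 with an estimated correlation). For Tnf the levels were 489.8 ± 43.0 FPKM with both and 505 ± 18.5 FPKM with LPS (limma adjusted p = 0.691), and for Acod1 1411 ± 170.1 FPKM and 1550.1 ± 53.6 FPKM (limma adjusted p = 0.358). With median-of-ratios scaling both were called lower, with adjusted p of 0.0319 and 0.0301. Interferon-stimulated genes were lower in 30 of 42 members (31 adjusted over the list alone, camera adjusted p = 9.52e-13, and adjusted p = 0.186 with an estimated correlation), with Cxcl9 at -2.61. The feedback inhibitors were lower in 15 of 27 members (15 adjusted over the list alone, camera adjusted p = 1.11e-04, and adjusted p = 0.192 with an estimated correlation), with Socs1 at -3.59. MHC class II genes were lower in 6 of 6 members (6 adjusted over the list alone, camera adjusted p = 4.83e-06, and adjusted p = 0.156 with an estimated correlation), with H2-Ab1 at -2.47 ± 0.09. MHC class I genes were lower in 11 of 15 members (11 adjusted over the list alone, camera adjusted p = 1.49e-06, and adjusted p = 0.242 with an estimated correlation). The macrophage identity list was lower in 9 of 17 members (9 adjusted over the list alone, camera adjusted p = 0.00495, and adjusted p = 0.267 with an estimated correlation), including the F4/80 gene Adgre1 at -2.89 ± 0.11 and the Fc receptor Fcgr1 at -3.13 ± 0.09. Csf3r was lower (-3.55) and S100a8 higher (0.98).

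The cell cycle inhibitor Cdkn1c (chromosome 7, 143458339 to 143461050) was higher in LPS+4-OHE1 than in LPS at 24 h (6.34 ± 0.18), where LPS alone gave 0.983 ± 0.390 FPKM. The ATF4 list was higher in 29 of 32 members (30 adjusted over the list alone, 28 under both scalings, camera adjusted p = 1.64e-09, and adjusted p = 0.191 with an estimated correlation), and Gdf15 rose by 3.40 and Hspa1a by 5.79. NRF2 targets were higher in 31 of 42 members (32 adjusted over the list alone, 25 under both scalings, camera adjusted p = 3.71e-06, and adjusted p = 0.267 with an estimated correlation). Nqo1 rose by 2.40 and Gclc by 2.38. Mki67 was lower (-2.55), while the cell cycle list went both ways, with 14 of 32 members (14 adjusted over the list alone, 9 under both scalings) higher, 4 of 32 members (5 adjusted over the list alone) lower and a median of 0.19 (camera adjusted p = 0.969, and adjusted p = 0.984 with an estimated correlation). By limma with Benjamini-Hochberg adjustment, 4420 genes were higher and 1661 lower, or 2577 and 2963 with median-of-ratios scaling, which moved the median gene from 0.17 to -0.02. Under both, 2577 were higher and 1657 lower.

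The interaction at 24 h was negative for 26 of 32 members (28 adjusted over the list alone) of the inflammatory list (camera adjusted p = 1.55e-17, and adjusted p = 0.0884 with an estimated correlation), with Saa3 at -9.86 ± 0.51 and Il1b at -6.14 ± 0.44. It was positive for 32 of 32 members (32 adjusted over the list alone) of the cell cycle list (camera adjusted p = 7.86e-18, and adjusted p = 0.0898 with an estimated correlation), with Ccnb2 at 4.39. For 20 of these 32, and for 345 of all genes with a positive interaction at 24 h, the sum of the single effects lay below the value of 0 FPKM. This fixed in advance 2.86 of the interaction of Ccnb2. For the other 12 members the sum lay above that value. It was close to it for some of them, as for Tyms (-0.80) and Mcm2 (-0.77), and far above for others, as for Pcna (4.37). The interaction was negative for 17 of 19 members (18 adjusted over the list alone) of the ER chaperones (camera adjusted p = 2.68e-11, and adjusted p = 0.0898 with an estimated correlation), with Hyou1 at -1.31. The interferon-stimulated genes had a median of 0.17 (camera adjusted p = 0.761, and adjusted p = 0.93 with an estimated correlation), with Cxcl10 at 1.59 ± 0.18. Limma with Benjamini-Hochberg adjustment gave 3089 positive and 1753 negative interactions, or 2397 and 2423 with median-of-ratios scaling (median gene 0.10 and -0.01), 2395 and 1751 of them shared. In LPS+4-OHE1 against 4-OHE1 at 24 h, Ccl5 rose by 10.00, Acod1 by 9.76 and Irf7 by 7.23, and Ccnd1 was lower (-3.65). Interferon-stimulated genes rose there in 42 of 42 members (42 adjusted over the list alone, camera adjusted p = 2.37e-55, and adjusted p = 0.00959 with an estimated correlation). Inflammatory genes rose in 25 of 32 members (25 adjusted over the list alone, camera adjusted p = 2.73e-22, and adjusted p = 0.0145 with an estimated correlation). The limma calls with Benjamini-Hochberg adjustment were 1338 higher and 4960 lower, or 2594 and 2398 with median-of-ratios scaling (median gene -0.22 and near 0), 1337 and 2397 of them shared.

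The responses to LPS alone and 4-OHE1 alone were compared with each other at each time. At 6 h, 641 genes were higher in both and 3898 lower in both, where independent lists of the same sizes would share 374 and 3329, and 1770 were called in opposite directions. At 24 h, 1270 were higher in both and 2173 lower in both, where independent lists would share 667 and 1382, and 1172 were opposite. With median-of-ratios scaling, 1742 were higher and 1935 lower in both at 6 h (1197 and 1187 for independent lists, 1532 opposite), and 1760 and 2084 at 24 h (960.3 and 1052, 815 opposite). Restricted to changes of at least 2-fold, 891 genes were shared in direction at 6 h and 610 at 24 h. Both comparisons used the same 3 control libraries. Unchanged groups simulated against them shared 0 calls, which was fixed in advance, since almost no gene is called without an effect. Across genes, which are not independent replicates, the covariance of the log2 differences was 0.305 at 6 h against 0.0138 in the simulations, and 0.422 at 24 h against 0.0132. With the controls divided 1 and 2 between the comparisons in the 6 possible ways, so that no library entered both, the covariance was 0.288 to 0.293 at 6 h and 0.407 to 0.418 at 24 h. Then 520 to 559 genes were higher and 2944 to 3520 lower in both at 6 h (278 to 322 and 2456 to 2839 for independent lists), and 928 to 984 and 1434 to 1849 at 24 h (415 to 489 and 859.7 to 1053), with the lone control assumed to vary like the other groups.

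The effects at 24 h were set against those at 6 h in a fit of all 24 libraries over 11544 genes. For LPS, 39 of 45 members (40 adjusted over the list alone) of the interferon-stimulated list had a more negative effect at 24 h (camera adjusted p = 4.78e-23, and adjusted p = 0.0786 with an estimated correlation), with Rsad2 at -5.98 ± 0.28 and Cxcl10 at -5.57 ± 0.27. Cell cycle genes had a more negative effect in 27 of 32 members (27 adjusted over the list alone, camera adjusted p = 5.53e-15, and adjusted p = 0.0786 with an estimated correlation), with Ccnb2 at -4.37 ± 0.22. The protease inhibitor Slpi (6.04 ± 0.24), the arginase Arg1 (4.84 ± 0.27) and Nqo1 (1.74 ± 0.13) had more positive effects of LPS at 24 h. For 4-OHE1, the effect was more negative at 24 h for Hmox1 (-2.76 ± 0.12), Gdf15 (-3.08 ± 0.15) and Vegfa (-2.07 ± 0.17), and more positive for Nqo1 (2.35 ± 0.13) and Slc6a12 (3.60 ± 0.21). The hypoxia targets had a more negative effect in 10 of 16 members (10 adjusted over the list alone, camera adjusted p = 2.95e-07, and adjusted p = 0.00104 with an estimated correlation). The ATF4 list had a more negative effect in 23 of 33 members (24 adjusted over the list alone, camera adjusted p = 7.78e-12, and adjusted p = 0.115 with an estimated correlation). For LPS+4-OHE1 against LPS, the effect was more positive at 24 h in 28 of 35 members (28 adjusted over the list alone) of the inflammatory list (camera adjusted p = 4.67e-06, and adjusted p = 0.251 with an estimated correlation), with Il1b at 3.29 ± 0.37 and Tnf at 2.33 ± 0.12. The fit used limma with Benjamini-Hochberg adjustment and gave 4827 genes with a more positive and 1951 with a more negative effect at 24 h for LPS, 4293 and 1925 for 4-OHE1, and 2929 and 2970 for LPS+4-OHE1 against LPS. With median-of-ratios scaling these were 2759 and 3268, 2506 and 2930, and 3092 and 2973. The authors made the tables of the 6 h and 24 h libraries separately.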

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

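The tests of the share of the 10 genes with most reads, of granulocytes, and of which drawn splits kept a pair of groups intact were chosen only after the result was seen.

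The effects of LPS at 24 h and 6 h differed for 6778 genes, those of 4-OHE1 for 6218, and those of 4-OHE1 in LPS-treated cells for 5899, each by limma's test of the difference. For LPS these included Slpi (6.04), Arg1 (4.84), Nqo1 (1.74), Rsad2 (-5.98), Cxcl10 (-5.57) and Ccnb2 (-4.37), as log2 effects at 24 h minus 6 h. For 4-OHE1 they included Slc6a12 (3.60), Nqo1 (2.35), Hmox1 (-2.76), Gdf15 (-3.08), Ccnb2 (-2.60) and Vegfa (-2.07). For LPS+4-OHE1 against LPS they included Cdkn1c (3.48), Il1b (3.29), Tnf (2.33), Arg1 (-4.64), Sesn2 (-3.38) and Vegfa (-2.83). Arg1 averaged 17.3 ± 1.98 FPKM with LPS at 24 h and at most 0.182 ± 0.123 FPKM in the other 7 groups.

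At 6 h, inflammatory genes had far more negative interactions than interferon-stimulated genes, with a difference of list medians of -4.39. Their stronger induction by LPS, as measured on this scale, did not account for the whole difference. After the trend of the interaction on the LPS response over 953 induced genes was removed (slope -0.42), it was -3.27 (95% interval over resampled genes -3.98 to -2.48, which treats genes as independent). The pseudocount understates the LPS response of genes near 0 FPKM in control, such as Il1b and Il6, so the trend may remove too little for them. The LPS+4-OHE1 library that stood apart does not account for the difference, which was -4.47 without that library. The interaction also subtracts the effect of 4-OHE1 alone, which lowered most interferon-stimulated genes and raised some inflammatory genes, and this adds to the gap. In LPS+4-OHE1 against LPS itself, most members of both lists were lower, as were most feedback inhibitors and 781 of the 953 induced genes. A stronger action of 4-OHE1 on the inflammatory than on the interferon arm of the LPS response may therefore be considered. It is a hypothesis that was found and tested in the same libraries.

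With LPS at 6 h, many more genes were called lower than higher. The 10 genes with most reads in each library held 9.99% to 10.05% of gene reads with LPS and 10.7% to 11.1% in control, a difference of -0.891 percentage points. A few dominant genes thus did not hold most of the reads. Induced genes may have replaced others among these 10, so what a few of them added to the shift was not measured. The 953 induced genes took 32.2% ± 0.0289 (SD, n = 3) of gene reads with LPS and 4.80% ± 0.0188 in control, which lowers the share left for other genes by a log2 ratio of -0.49, beside a median change of -0.69 in those genes. The gap between these 2 values decides nothing, although it had been set as a bound, because the genes were divided by the unscaled change, and 662 of the others rose at least 2-fold with median-of-ratios scaling. Reads taken by induced genes and a lower content of most transcripts per cell cannot be told apart, since total RNA per cell is not known here.

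The 5 of 15 neutrophil markers that passed the filter rose with LPS at 24 h. Granulocytes in the cultures were argued against, since S100a9, Ngp, Ltf and Retnlg, abundant in those cells, averaged at most 0.201 FPKM there, beside 48.8 ± 9.87 FPKM for S100a8. Of the markers that rose, S100a8 (2.75 ± 0.381 FPKM), Mmp8 (8.31 ± 0.610) and Csf3r (2.01 ± 0.0412) were present in control as well. Expression of these markers by the macrophages may be proposed as a hypothesis only.

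For the 8 comparisons of 3 libraries with 3, 1 of the 10 splits, the real one, gave as many calls; 10 splits are too few for a share under 0.05. The real and highest other counts were 9355 and 2 (LPS), 7202 and 2 (4-OHE1), 7544 and 1 (LPS+4-OHE1 against LPS) and 6701 and 2 (LPS+4-OHE1 against 4-OHE1) at 6 h, and 8211 and 0, 5928 and 2, 6081 and 1, and 6298 and 3 at 24 h. Every other split mixed both treatments within its groups, which puts their difference into the spread. The low counts of those splits were thus fixed in advance, whatever the cause of the real difference. Of 100 drawn splits, the real one included, 2 gave as many interaction calls at 6 h (real 6734, highest other 7732) and 1 at 24 h (4842 and 2816). For the time difference of 4-OHE1, 2 did (6218 and 7582), and these shares were under 0.05. The shares for the time differences of LPS (6 of 100, 6778 and 9621) and of LPS+4-OHE1 against LPS (6 of 100, 5899 and 6606) were not. The other splits with as many calls (1, 0, 5, 1 and 5, in the order 6 h and 24 h interaction, then LPS, 4-OHE1 and LPS+4-OHE1 against LPS) all kept a pair of the groups whole, and so kept the difference between them. Splits that kept none gave at most 3 calls, which the same mixing fixed in advance. The shares thus depend on how many splits with a whole pair were drawn, and do not decide whether chance is excluded.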

How the results depend on the processing

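Limma's voom on recovered reads and the division of the controls were chosen only after the result was seen. Over all alternatives, 307 values of the comparisons stayed close to the reported ones and 27 moved. For counts of genes, close refers to the total called and not to the direction of the calls. With median-of-ratios scaling, LPS at 6 h went from 1792 genes higher and 7563 lower to 4129 and 3761, with 1097 opposite calls. Of the values of single genes, 3028 kept their direction and call, 5 gained a call, 1 lost it and 3 reversed. These 3 were of Nqo1 with LPS at 6 h, higher with scaling (0.32), voom (0.33) and in the authors' deposited tables (0.31). With median-of-ratios scaling LPS+4-OHE1 against 4-OHE1 at 6 h gave 4317 genes in place of 6701, and moved the median gene from -0.28 to -0.01. Of 5576 genes called lower without scaling 2000 stayed lower, and of 1125 called higher 1124 stayed higher. The calls lost were thus mostly of genes called lower. Asking for at least 2-fold changes left 891 shared genes at 6 h and 610 at 24 h, by construction.

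Lists called by camera with an estimated correlation, and by fry, which does not compare a list with other genes, numbered, at 6 h, 3 and 32 for LPS (12 with the preset correlation), 5 and 26 for 4-OHE1 (15), 0 and 28 for LPS+4-OHE1 against LPS (14), 5 and 24 against 4-OHE1 (10) and 3 and 23 for the interaction (10). At 24 h they were 5 and 30 (16), 1 and 23 (12), 0 and 25 (18), 4 and 25 (16) and 0 and 21 (14) in the same order. For the time differences they were 2 and 31 (10), 2 and 26 (13) and 2 and 26 (13).

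Leaving out each library in turn gave, at 6 h, 8829 to 9038 genes for LPS, 6425 to 6698 for 4-OHE1, 6910 to 7673 for LPS+4-OHE1 against LPS, 5797 to 6951 against 4-OHE1 and 6088 to 7077 interactions. At 24 h it gave 7614 to 8110, 4987 to 5763, 5404 to 5843, 5543 to 6110 and 4205 to 4965, and for the time differences 6353 to 6759, 5779 to 6044 and 5508 to 6031. LPS-raised genes lowered in LPS+4-OHE1 were 77.8% to 82.0% and 63.8% to 68.6%.

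Calls of Ifit1 were gained in LPS+4-OHE1 against LPS at 6 h without LPS+4-OHE1 replicate 3 (0.45) and lost in the interaction with voom (1.75, adjusted p = 0.0556); at 24 h Tnf and Acod1 became lower with scaling (-0.26 and -0.35) and with voom (-0.26 and -0.35). The replicate block gave 9283 genes for LPS at 6 h and 8293 at 24 h, and no count of genes or lists moved by over 1.5 times; same-numbered libraries deviated together with correlations of -0.14 to 0.08 at 6 h and -0.09 to 0.27 at 24 h, and 4 and 5 of 12 libraries correlated best with their own number. The authors' deposited tables called 4242 genes higher and 3940 lower for LPS at 6 h and 3864 and 3761 at 24 h, and for 4-OHE1 3669 and 3263, then 2800 and 2987. Not run were the alternatives planned for raw counts (DESeq2, edgeR's size factors, filter and test), for which the recovered reads might have served. The authors' tables were not used for the time differences, which they do not hold. Genes with a few reads per group limit what single differences show.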

Other observations

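No test in this part was chosen only after the result was seen.

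Of OXPHOS complex I genes, 28 of 37 members (27 adjusted over the list alone, 0 under both scalings) were lower with LPS at 6 h (camera adjusted p = 0.831, and adjusted p = 0.96 with an estimated correlation), of complexes II to V 21 of 36 members (18 adjusted over the list alone, 0 under both scalings, camera adjusted p = 0.876, and adjusted p = 0.96 with an estimated correlation), and of TCA cycle genes 22 of 25 members (22 adjusted over the list alone, 6 under both scalings, camera adjusted p = 0.335, and adjusted p = 0.783 with an estimated correlation). Among all 11098 genes tested 7563 were called lower in that comparison, a larger share than in complexes II to V. Glycolysis genes, which break down glucose, were higher with 4-OHE1 at 6 h in 15 of 23 members (15 adjusted over the list alone, camera adjusted p = 1.69e-05, and adjusted p = 0.261 with an estimated correlation), and lysosome genes in 21 of 31 members (21 adjusted over the list alone, camera adjusted p = 1.13e-06, and adjusted p = 0.122 with an estimated correlation). Metal response genes were higher there in 4 of 5 members (4 adjusted over the list alone, camera adjusted p = 8.12e-04, and adjusted p = 0.0433 with an estimated correlation), and mitochondrial chaperones and proteases in 11 of 21 members (11 adjusted over the list alone, 8 under both scalings) with 4-OHE1 at 24 h (camera adjusted p = 0.101, and adjusted p = 0.547 with an estimated correlation). Mitochondrial biogenesis and dynamics genes were lower with 4-OHE1 at 6 h in 12 of 20 members (12 adjusted over the list alone, 9 under both scalings, camera adjusted p = 0.298, and adjusted p = 0.468 with an estimated correlation), and mitochondrial antioxidants in 4 of 14 members (4 adjusted over the list alone, camera adjusted p = 0.951, and adjusted p = 0.976 with an estimated correlation).

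In LPS+4-OHE1 against LPS at 24 h, p53 targets were higher in 12 of 15 members (12 adjusted over the list alone, 9 under both scalings, camera adjusted p = 0.00495, and adjusted p = 0.132 with an estimated correlation), and alternative activation markers lower in 3 of 6 members (4 adjusted over the list alone, camera adjusted p = 0.0239, and adjusted p = 0.186 with an estimated correlation). LXR targets, genes of cholesterol efflux and of lipid synthesis, were lower with LPS at 24 h in 11 of 14 members (11 adjusted over the list alone, 7 under both scalings, camera adjusted p = 0.27, and adjusted p = 0.398 with an estimated correlation), although the exporter Abca1 rose by 4.09. Ribosomal proteins were lower there in 7 of 29 members (2 adjusted over the list alone, 1 under both scalings, camera adjusted p = 0.421, and adjusted p = 0.92 with an estimated correlation). Among all 11185 genes tested 5980 were called lower there, a larger share than of the ribosomal proteins. Of markers of other cells with LPS at 24 h, dendritic cell markers were higher in 1 of 2 members (1 adjusted over the list alone, camera adjusted p = 0.109, and adjusted p = 0.243 with an estimated correlation), mast cell and basophil markers lower in 1 of 1 members (1 adjusted over the list alone, camera adjusted p = 0.292, and adjusted p = 0.483 with an estimated correlation) and stromal and endothelial markers in 1 of 5 members (1 adjusted over the list alone, camera adjusted p = 0.966, and adjusted p = 0.976 with an estimated correlation).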
